A study of Homo sapiens with 12 samples.

How the data were processed

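Total RNA from MCF7 and HCT116 cells sorted into ROS-high and ROS-low gates was labelled with biotin by a one-cycle protocol and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are MAS5 intensity values on a linear scale, per the submitters' processing notes, which name MAS5 without a version. MAS5 combines the probes of a feature into one background-corrected signal per array. The array model, the probe grouping and any filter are not given in the sources used here. The deposited table has 18394 rows and 12 columns, 1 per array. All 18394 rows carry a human Ensembl gene identifier with the suffix that probe sets have, so each row is 1 gene and no choice between probe sets of a gene was needed. The 2% trimmed mean of each array lay between 98.7 and 98.9, so the intensity values had been scaled to a common level before they were deposited. No value was at or below 0.

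The files do not pair these identifiers with gene names. The reference gene table given holds 59792 genes and no Ensembl identifiers, and 0 of the 18394 rows could be matched to a symbol. Genes are therefore not named, and at most 2 identifiers that rose and 2 that fell are printed. The 31 gene lists and the 16 single genes planned before the data were examined are written as symbols and were not analysed here. A planned comparison of RNA quality controls was not run, because the table held 0 control rows. In place of the lists, cell cycle marker sets keyed by Ensembl identifier were taken from the human marker pairs that come with an R package for single-cell data. These pairs were derived from human embryonic stem cells sorted by phase and hold cell cycle genes only. For each phase (G1, S and G2/M), the 50 genes present in the table that were most often the higher member of a pair, net of the times they were the lower, formed a set. The remaining marker genes formed a set called other cell cycle genes. Of 1314 genes in the pairs, 1165 were in the table and 1079 were among the genes tested: 50 G1, 46 S, 49 G2/M and 934 other genes. The sets were chosen after seeing the data, though before any set was tested. A gene belongs to a set because of its behaviour in stem cells, which need not hold in MCF7 or HCT116 cells.

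Signals were transformed as log2(signal + 4.60), the pseudocount being the 20th percentile of all values, which understates the change of dim genes. No further scaling was applied. The 40% of genes with the lowest mean over all 12 arrays were left out, and 11036 genes were tested. Linear models with a mean for each of the 4 groups were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, on 8 residual degrees of freedom. All differences are ROS low minus ROS high. The contrasts were the difference in MCF7, the difference in HCT116, the mean of both, and HCT116 minus MCF7 (the difference between lines). P-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. Sets were tested with limma's camera, which compares a set with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 4 sets. As a second test, each array received a score per set, the mean over the set's genes of log2 signal minus the gene's mean in that line. Scores were compared by two-sided exact permutation of the gate labels within each line. A single line of 3 against 3 arrays cannot give a p under 0.1, and both lines together have 400 assignments. Exact sign flips of the 6 pair differences, chosen after seeing the data, have 64 assignments. The number of arrays limits the precision.

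The rule for the genes to print was set before the data were examined: those with the highest and lowest mean difference of both lines among genes called for that mean that also had an unadjusted p under 0.05 and the same sign in each line. Only the first 2 in each direction are printed.

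The labels number the replicates 1 to 3 in every group. Deviations from the group means were correlated between the ROS-low and ROS-high arrays of a line. Arrays of the same line and number correlated at 0.19 to 0.65 in all 6 pairs (mean 0.42), against a mean of -0.20 for the 12 pairs of different numbers in a line. Deviations of the 3 arrays of a group sum to 0, so the negative mean for different numbers largely follows from the positive one for the same number. Each of the 6 ROS-low arrays correlated best with the ROS-high array of its own number. For the same reason, these matches are not independent within a line. The numbers were therefore treated as pairing the samples within a line. The pairing comes from the labels' numbers and this check, since the labels do not say what a number shares. The planned fit without the numbers gives the main values, and values with the replicate number as a block are printed beside them where they change a call or move a count by over 1.5 times.

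The steps were tested on simulated data made from the real arrays' means and spread over 11036 genes, with 100 genes of each size changed. Of genes changed by 1 on the log2 scale, 62% were recovered in MCF7, 56% in HCT116, 83% for the mean of both lines and 31% for the difference between lines. At a change of 2, the shares were 93%, 89%, 98% and 75%. Between 5 and 12 unchanged genes were called per contrast. The simulated noise was drawn independently for each gene and array, without differences between replicate numbers or correlation between genes. The real arrays of the same number deviate together, so these shares and false calls need not hold for them. The alternatives tried were other scalings, pseudocounts and filters on dim genes, a fit without the trend, array weights, the replicate block, fits of a single line, fits without each array and, added after seeing the data, a fit without both MCF7 arrays numbered 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.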

Results

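Gene expression was measured on 12 Affymetrix arrays in 2 human cancer cell lines, MCF7 (breast adenocarcinoma, here the MCF7-BOS subline) and HCT116 (colorectal carcinoma). Cells were loaded with 2.5 µM DCFDA for 30 min, washed for 1 hour and separated on a cell sorter into a gate of high and a gate of low dye signal. DCFDA is a dye that becomes fluorescent when it is oxidised inside the cell, so its brightness serves as a readout of reactive oxygen species (ROS). Each of the 4 groups (MCF7 ROS high, MCF7 ROS low, HCT116 ROS high and HCT116 ROS low) had 3 arrays. The series title places the comparison in a study of asymmetric cancer cell division and the kinase AKT. The comparisons ask which transcripts differ between ROS-low and ROS-high cells of a line and whether the lines share them. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

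The median signal of an array lay between 23.9 and 31.4, and the 25th percentile between 5.71 and 9.61. Arrays of different lines correlated at 0.736 to 0.796, which put 75.9% of the variance on the first principal component. Arrays of the same group correlated at a median of 0.970 and arrays of different gates in a line at 0.966. The lowest mean correlations with their own group were 0.936 for MCF7 ROS low replicate 1 and 0.950 for MCF7 ROS high replicate 1. These 2 arrays lay at 42.3 and 30.9 on the second principal component (7.19% of the variance), against -21.6 to -11.7 for the other MCF7 arrays.

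Averaged over both lines, markers of the G2/M phase, the late part of the cell cycle that ends in mitosis, were lower in ROS-low cells. Of the 49 G2/M markers tested, 23 fell, none rose and 26 did not pass. Their median log2 difference was -0.60, a median fold of 1.52, with quartiles at -1.22 and -0.09. The set's score was lower in the ROS-low array of all 6 pairs, by a mean of -0.68 ± 0.28 on the log2 scale (SD over pairs, n = 6; exact permutation over 400 assignments, p = 0.005, the smallest they can give, adjusted p = 0.01 over 4 sets). The set differed from all other genes by camera at adjusted p = 4.1e-30 with the preset correlation and adjusted p = 0.00513 with an estimated correlation. The 46 S-phase markers, genes highest during DNA replication, held 0 called genes, and their median was -0.06. Camera put the S set lower at adjusted p = 0.00378, a call lost with an estimated correlation (adjusted p = 0.303). It was also lost without MCF7 ROS low replicate 2 (mean difference -0.05, camera adjusted p = 0.159). Without MCF7 ROS low replicate 1 the mean difference was -0.21. The exact permutation of the S score gave p = 0.225. That permutation leaves out the pairing by replicate number. The S score was lower in the ROS-low array of 5 of the 6 pairs, by a mean of -0.13 ± 0.12 (SD over pairs), and exact sign flips of the pair differences gave p = 0.0625 (adjusted p = 0.0833 over 4 sets). Among the 50 G1 markers, 4 fell and 1 rose, with a median of -0.02 (camera adjusted p = 0.0648; exact permutation p = 0.13; exact sign flips p = 0.0938). Among the 934 other cell cycle genes, 57 fell and 6 rose. Their median was -0.02, and camera gave adjusted p = 4.44e-05, or adjusted p = 0.00513 with an estimated correlation. Their score, like that of the G2/M set, was lower in all 6 pairs (-0.20 to -0.04, mean -0.11; exact permutation p = 0.005, adjusted p = 0.01). For both sets, exact sign flips gave p = 0.031, the smallest that 6 pairs allow, which did not pass over 4 sets (adjusted p = 0.0625). With the replicate number as a block, 10 S markers fell and 2 rose, 10 G1 markers fell and 7 rose, and 143 of the other cell cycle genes fell and 29 rose.

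**Figure D1:**
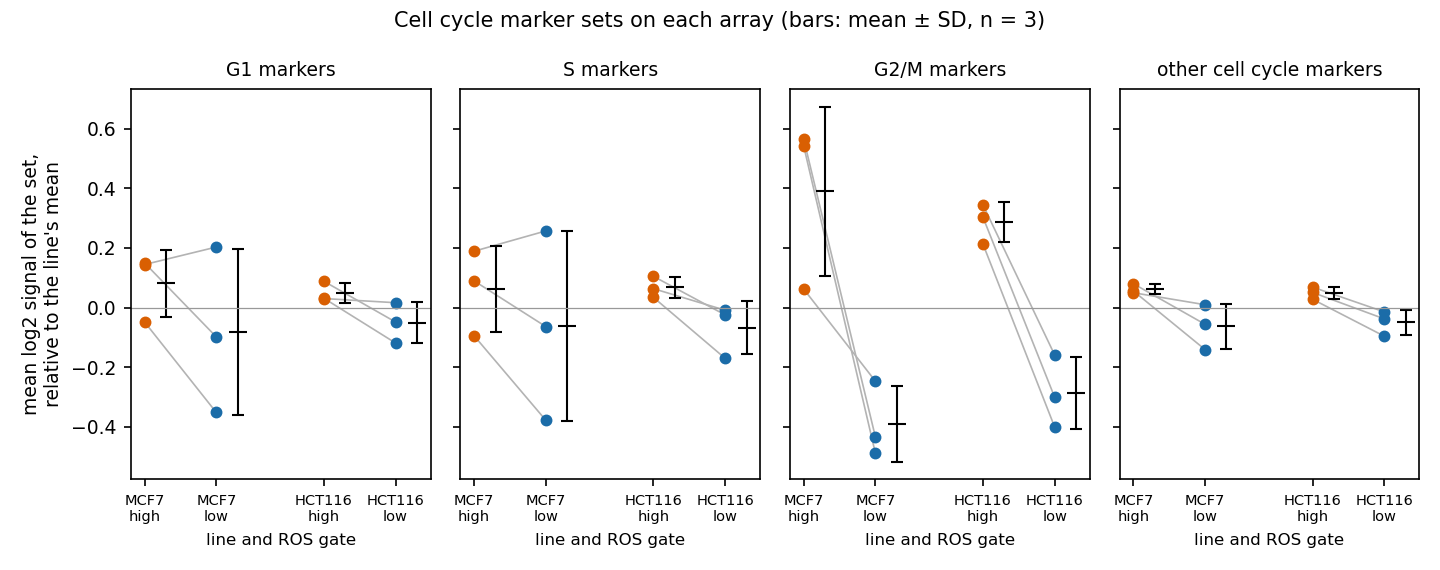
Score of each cell cycle marker set on each array, as the mean log2 signal of the set's genes relative to the line's mean, for ROS-high (orange) and ROS-low (blue) arrays of MCF7 and HCT116. Grey lines join arrays with the same replicate number and black bars give the mean and SD of 3 arrays. The G2/M score was lower in the ROS-low array of all 6 pairs, with differences between -0.31 and -1.03, while the S scores of MCF7 had an SD of 0.32 (ROS low) and 0.14 (ROS high) against a difference between gates of -0.12.

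Over all genes, 160 of 11036 were called for the mean of both lines, 39 higher and 121 lower in ROS-low cells. The median difference of the called genes was 0.81 for those that rose and -1.05 for those that fell, and the median standard error over all genes was 0.15. Of the 121 genes that fell, 84 (69.4%) belonged to the cell cycle marker table, against 9.78% of all genes tested (Fisher's exact test, odds ratio 22.6, adjusted p = 2.44e-56 over 12 tests). Here and in each line, Fisher's test counts genes as independent, which genes measured on the same arrays are not. Its p-values therefore do not measure the spread between arrays. Of the 39 that rose, 7 (17.9%) did, which did not pass (adjusted p = 0.149). All 160 called genes had the same sign in both lines. With the replicate number as a block 780 genes were called, 350 higher and 430 lower, among them all 160, and 44.4% of those that fell were in the marker table. With array weights 551 genes were called, and leaving out 1 array moved the count to between 74 (without HCT116 ROS low replicate 1) and 276 (without MCF7 ROS low replicate 1). It was 328 without both MCF7 arrays numbered 1.

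Among the genes called for the mean, ENSG00000107968 was 1.93 ± 0.22 higher (log2, SE; adjusted p = 0.00267), the largest rise at the pseudocount used. Its signal went from 37.2 ± 7.7 to 126 ± 16.3 in MCF7 and from 8.91 ± 4.4 to 58.8 ± 25.2 in HCT116 (mean ± SD, n = 3 each, ROS high to ROS low). Its HCT116 ROS-high signals reached down to 4.41, below the pseudocount of 4.60, and with the median signal as pseudocount its rise was 1.23, below the 1.62 of ENSG00000153234. It was not tested with the dimmest 60% left out. ENSG00000153234 was 1.74 ± 0.14 higher (adjusted p = 0.000374), from 81.8 ± 23.0 to 181 ± 15.2 in MCF7 and from 476 ± 76.2 to 2445 ± 438 in HCT116. ENSG00000170312 fell most, with a difference of -1.87 ± 0.22 (adjusted p = 0.00303), from 576 ± 143 to 176 ± 50.4 in MCF7 and from 674 ± 160 to 163 ± 61.9 in HCT116. ENSG00000175063 followed at -1.68 ± 0.18 (adjusted p = 0.00267), from 2070 ± 661 to 674 ± 202 in MCF7 and from 1661 ± 154 to 490 ± 65.5 in HCT116. Both genes that fell are in the cell cycle marker table and neither that rose is. All 4 were also called in each line, with adjusted p between 0.0308 and 0.0402 in MCF7 and between 0.000635 and 0.0277 in HCT116. In a fit of the 6 MCF7 arrays alone their adjusted p in MCF7 was 0.300 to 0.326, and leaving out single arrays ended the call within a line for all of them except ENSG00000153234 in HCT116.

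**Figure D2:**
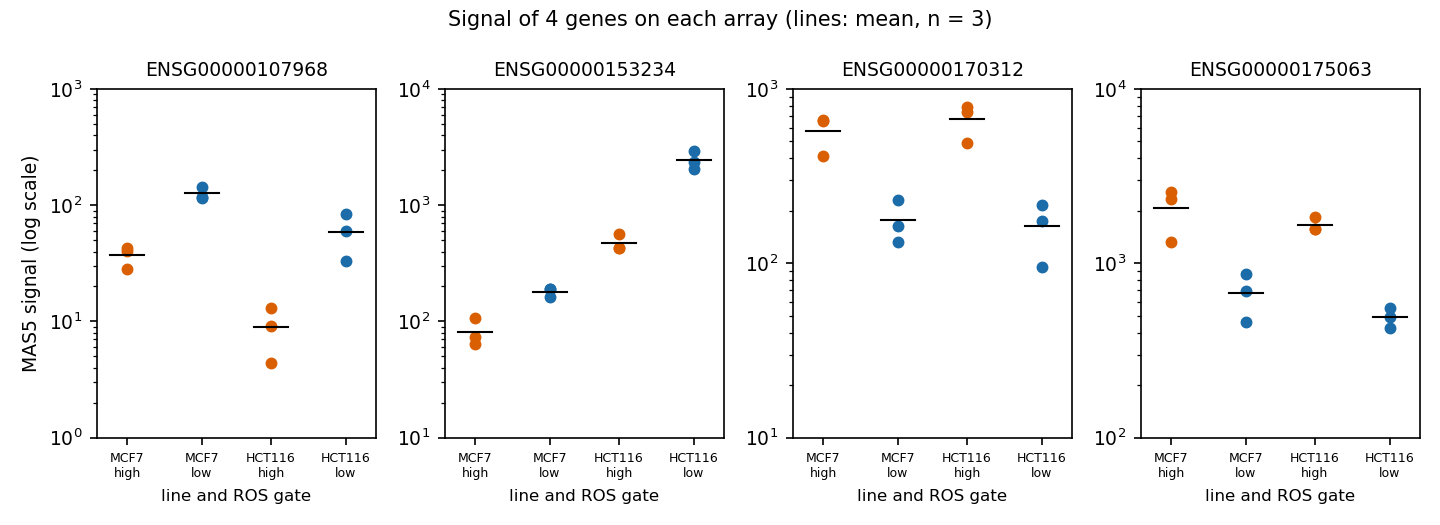
MAS5 signal on a log axis of the 2 genes that rose and the 2 that fell chosen by the rule for the mean of both lines, on each array of the 4 groups (orange, ROS high; blue, ROS low; black lines, mean of 3 arrays). In each line the 3 ROS-low arrays lie apart from the 3 ROS-high arrays for all 4 genes. The genes were chosen on this same difference, so the separation is not added support. In a single line, chance separates 3 arrays from 3 for 10% of genes not chosen in this way.

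In MCF7, 13 of the 49 G2/M markers fell in ROS-low cells and none rose. Their median difference was -0.76, 42 of them were negative, and 26 passed when adjusted over the list alone. The G2/M score was -0.39 ± 0.13 in ROS-low and 0.39 ± 0.28 in ROS-high arrays (SD, n = 3), with the exact permutation p at 0.1, the smallest that 3 against 3 arrays allow. ROS high replicate 1, of the pair that stands apart on the second component, scored 0.06 against 0.56 and 0.54 in the other ROS-high arrays, and the pair differences were -0.31 for replicate 1 and -0.999 and -1.03 for the others. Camera gave adjusted p = 5.21e-29, and adjusted p = 0.00574 with an estimated correlation. The G1 set had 4 genes that fell and none that rose. Its mean difference was -0.16 and its median 0.01, so the 2 differed in sign. Its camera call in the direction of the mean (adjusted p = 0.0326) was lost with an estimated correlation (adjusted p = 0.318) and with the replicate block (adjusted p = 0.0557). The call was also lost after quantile normalization (camera adjusted p = 0.0556) and median centring (0.0677). Leaving out 1 array moved the mean difference to between -0.31 (without MCF7 ROS low replicate 1) and -0.03 (without MCF7 ROS low replicate 2, camera adjusted p = 0.868). The S set (median -0.04, camera adjusted p = 0.0127) held no called gene, and its call was lost with an estimated correlation (adjusted p = 0.321). The other cell cycle genes held 31 that fell and 2 that rose (median -0.03, camera adjusted p = 3.39e-05). In the fit with the replicate block, 5 G1 markers fell and 2 rose, 2 S markers fell and 1 rose, and 78 other cell cycle genes fell and 17 rose.

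In all, 76 genes were called in MCF7, 14 higher and 62 lower in ROS-low cells, and 902 had an unadjusted p under 0.05. The median differences were 1.44 and -1.41. Of the 62 that fell, 48 (77.4%) were in the marker table (odds ratio 33.0, adjusted p = 2.94e-36, Fisher's exact test). With the replicate block 418 genes were called, 190 higher and 228 lower, including all 76. Of the 228 that fell with the block, 111 (48.7%) were in the marker table (odds ratio 9.64), 26 of them G2/M markers. The count was 0 when the 6 MCF7 arrays were fitted alone, 3 with no filter on dim genes and 287 with array weights, leaving out 1 array moved it to between 1 and 165, and leaving out both arrays numbered 1 gave 224.

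In HCT116, 2 G2/M markers fell in ROS-low cells and none rose. The median of the 49 was -0.64, 42 of them were negative, and 23 passed when adjusted over the list alone. The G2/M score was -0.29 ± 0.12 in ROS-low and 0.29 ± 0.07 in ROS-high arrays (SD, n = 3; exact permutation p = 0.1, the smallest possible). Camera gave adjusted p = 5.55e-20, and adjusted p = 0.0331 with an estimated correlation. The G1 set (median -0.09, camera adjusted p = 0.322) did not pass. The S set (median -0.09, camera adjusted p = 0.028) held no called gene and its call was lost with an estimated correlation (adjusted p = 0.498). The other cell cycle genes held 1 that fell and 2 that rose (median -0.04, camera adjusted p = 0.00599, and adjusted p = 0.0331 with an estimated correlation). Their camera call was lost with no filter on dim genes (adjusted p = 0.0843). Under the replicate block, 4 S markers fell and 1 rose, 1 G1 marker fell and 3 rose, and 25 other cell cycle genes fell and 11 rose.

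For HCT116, 15 genes were called, 12 higher and 3 lower in ROS-low cells, with 732 at an unadjusted p under 0.05. This count and the 76 in MCF7 share 1 estimate of the spread. The order reversed with each line fitted alone (0 in MCF7, 52 in HCT116), so these counts do not rank the lines. Mean correlations with the own group were 0.936 to 0.967 for MCF7 arrays and 0.966 to 0.975 for HCT116 arrays. The median differences were 1.80 and -1.76. All 3 that fell were in the marker table (adjusted p = 0.00186, Fisher's exact test), as were 2 of the 12 that rose, which did not pass (adjusted p = 0.441). The replicate block gave 163 called genes, 81 higher and 82 lower, including all 15. Of the 82 that fell with the block, 35 (42.7%) were in the marker table (odds ratio 7.07, adjusted p = 1.24e-14), 5 of them G2/M markers. Of the 81 that rose with the block, 15 (18.5%) were in the marker table (odds ratio 2.11, adjusted p = 0.0229, Fisher's exact test). The count was 52 when the 6 HCT116 arrays were fitted alone, 30 with a pseudocount at the median signal and 248 with array weights, leaving out 1 array moved it to between 3 and 43, and leaving out both MCF7 arrays numbered 1 gave 110, of which 70 were lower.

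**Figure D3:**
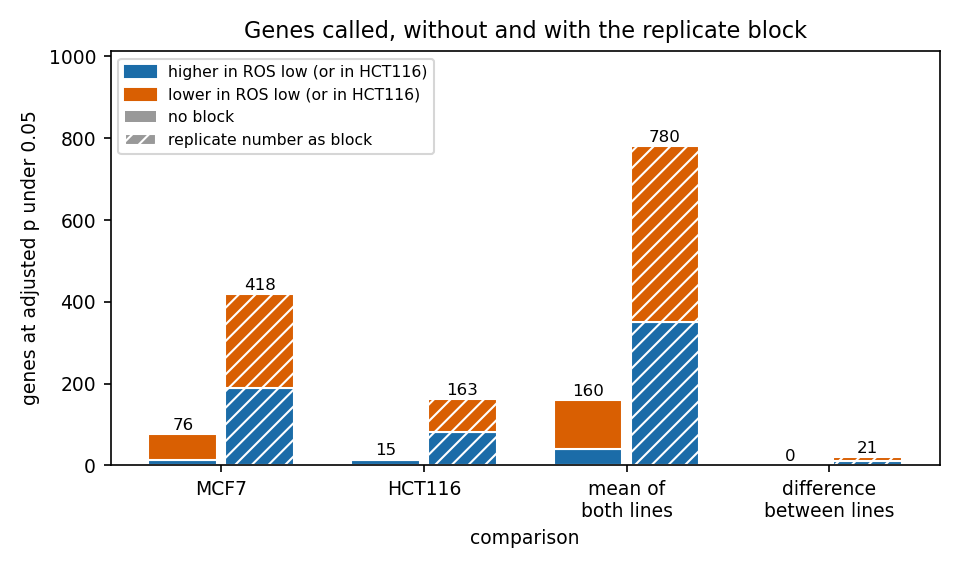
Number of genes called at an adjusted p under 0.05 in each comparison, without a block (plain bars) and with the replicate number as a block (hatched bars), split by direction. Counts were 76 and 418 in MCF7, 15 and 163 in HCT116, 160 and 780 for the mean of both lines, and 0 and 21 for the difference between lines.

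No gene's difference between the gates was called as different between the lines (0 of 11036 by limma, with 380 at an unadjusted p under 0.05 and a smallest adjusted p of 0.167). With the replicate block 21 genes were called, 11 with a higher difference in HCT116 and 10 with a higher one in MCF7, among them 1 G1 marker and 4 other cell cycle genes. ENSG00000153234 was one of these, with a rise larger by 1.22 in HCT116 (adjusted p = 0.0326 with the block and 0.839 without). With array weights 5 genes were called. The G2/M set fell less in HCT116, by a median of 0.22 (camera adjusted p = 0.00168), a call lost with an estimated correlation (adjusted p = 0.449). Its mean difference between the lines was 0.21, and 0.44, 0.10 and 0.08 without the MCF7 pair numbered 1, 2 and 3. Exchanging the line labels between the 6 pair differences gave an exact permutation p of 0.4 over 20 assignments.

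Across the 11036 genes, the differences in MCF7 and HCT116 correlated at a Pearson r of 0.356 and a Spearman rho of 0.268. Genes are not independent replicates, so no p-value is given. The lines share no arrays. The sign was the same for 58.2% of genes. Among called genes, 2 rose in both lines (0.0152 expected for independent lists) and 3 fell in both (0.0169 expected). These calls share 1 estimate of the spread, and no gene was called in both lines when each was fitted alone or without any 1 of 9 of the arrays. The replicate block gave 24 that rose in both and 33 that fell (1.39 and 1.69 expected), and array weights 10 and 90 (0.806 and 2.54 expected). Of the 62 genes that fell in MCF7, 61 had a negative difference in HCT116, with a median of -0.85. Of the 14 that rose in MCF7, 7 had a positive one (median 0.04). In the other direction, 11 of the 12 that rose in HCT116 had a positive difference in MCF7, with a median of 0.66, and all 3 that fell had a negative one. The correlation was 0.179 with no filter on dim genes and 0.489 with the dimmest 60% left out.

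**Figure D4:**
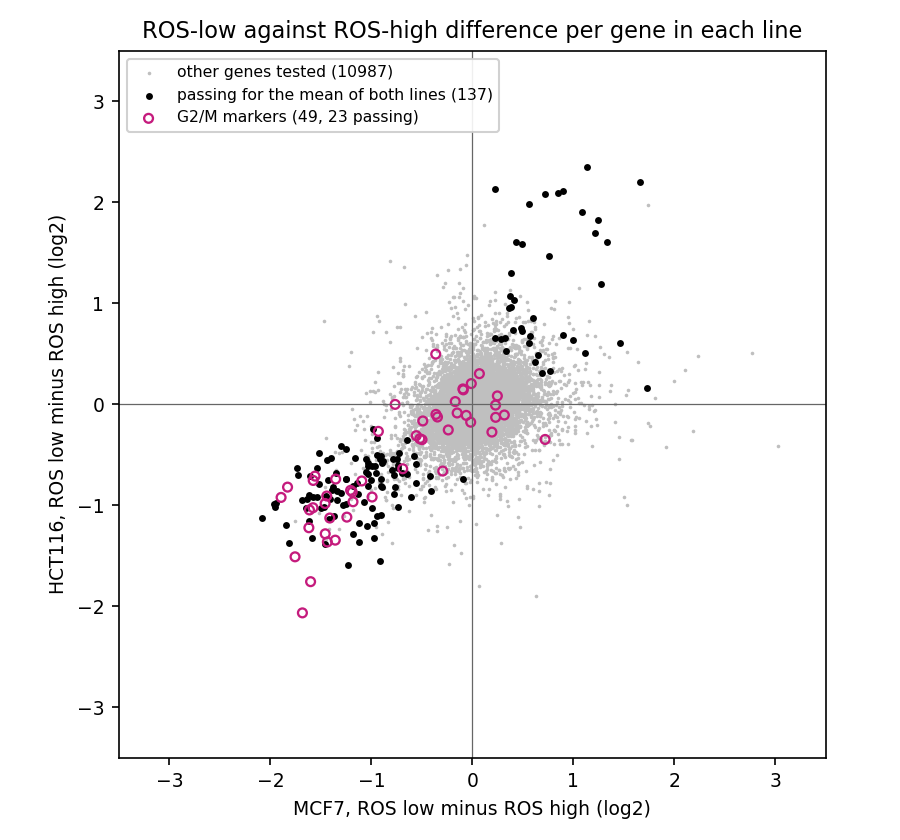
Log2 difference between ROS-low and ROS-high arrays of each of the 11036 genes tested, in MCF7 (x axis) and HCT116 (y axis). Black points are genes called for the mean of both lines outside the G2/M set and pink circles are the 49 G2/M markers, of which 23 were called. All 160 called genes lie in the lower left or the upper right, and across genes the Pearson r is 0.356.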

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

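The tests in this part were chosen after the result was seen. The mean G2/M difference was -0.78 in MCF7 and -0.57 in HCT116. The difference between the lines, 0.21 (HCT116 minus MCF7), passed camera's test with the preset correlation (adjusted p = 0.00168), which put it on the list of differences between cell lines. It did not pass with an estimated correlation (adjusted p = 0.449). Exchanging the line labels between the 6 pair differences gave an exact permutation p of 0.4 over 20 assignments, which cannot give a p under 0.1. The score's difference was -0.31 in the first MCF7 pair against -0.999 and -1.03 in the others, and -0.60, -0.61 and -0.50 in the HCT116 pairs. The difference between the lines was 0.08 without the MCF7 pair numbered 3, 0.10 without the pair numbered 2 and 0.44 without the pair numbered 1. Camera with the preset correlation gave adjusted p = 6.32e-14 for the 0.44. That test lost its call without MCF7 ROS high replicate 2 or 3 or ROS low replicate 3 (adjusted p = 0.0513, 0.110 and 0.0828). Without MCF7 ROS low replicate 2 the call was kept (camera adjusted p = 0.0355). Of the 49 markers, 0 were called singly. No biological explanation was tested.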

How the results depend on the processing

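The threshold of 1 log2 unit, leaving out both MCF7 arrays numbered 1 and all settings of the marker sets were chosen after seeing the data. The fall of the G2/M set was called by camera in MCF7, HCT116 and their mean under all 15, 15 and 14 alternatives. It was also called without each of the 12 arrays, and the mean of both lines lay between -0.89 and -0.45. Leaving out an array of the other line leaves a line's difference unchanged, so within a line only its own arrays could move it. Counts of genes moved more. The replicate block gave 418 genes in MCF7, 163 in HCT116, 780 for the mean and 21 for the difference between lines, and array weights gave 287, 248, 551 and 5. The block ended 1 set call, G1 in MCF7, and changed no other set call. Leaving out both MCF7 arrays numbered 1 gave 224 genes in MCF7, 110 in HCT116 (70 of them lower, against 3 of 15) and 328 for the mean. Fitting a line alone gave 0 genes in MCF7 and 52 in HCT116. No filter on dim genes gave 3 and 9 genes and a correlation between lines of 0.179, and leaving out the dimmest 60% gave 0.489. Without the variance trend MCF7 had 43 genes, with the median as pseudocount HCT116 had 30, and 85 genes of the mean changed by over 1 log2 unit. Spearman's rho was 0.268. The split into higher and lower went from 75.6% lower for the mean to 55.1% with the block and 57.5% with array weights, and between 75.5% and 80.0% under the other scalings. The cause was not tested, except that filters change the genes tested, and single lines the number of arrays and the estimate of the spread. Leaving out MCF7 arrays leaves the HCT116 differences unchanged. HCT116's count moved in those fits through the estimate of the spread that the 4 groups share, with its degrees of freedom.

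Leaving out 1 array, which also lowers the degrees of freedom, moved MCF7's count to 1 (ROS high replicate 2 or 3, ROS low replicate 3; in HCT116 ROS high replicate 1 or 3, ROS low replicate 1), 5 (MCF7 ROS low replicate 2), 139 and 165 (MCF7 ROS high and ROS low replicate 1), and 23, 27 and 43 (HCT116 ROS high replicate 2, ROS low replicates 2 and 3). HCT116's count went to 3 to 5 without its own ROS high arrays or its ROS low replicate 1 or 2, to 9 without its ROS low replicate 3 or MCF7 ROS low replicate 3, and to 33 and 43 without MCF7 ROS high and ROS low replicate 1. The count of the mean went to 74 to 106 without 8 of the arrays (in MCF7 ROS high replicates 2 and 3 and ROS low replicate 3; in HCT116 all except ROS low replicate 3) and to 276 without MCF7 ROS low replicate 1. The difference between lines had 2 genes without MCF7 ROS low replicate 2 and 0 otherwise, and the correlation lay between 0.282 and 0.368. The G2/M difference between lines was 0.12 to 0.37 and lost its call without MCF7 ROS high replicate 2 or 3, MCF7 ROS low replicate 3 or HCT116 ROS low replicate 3, and at 0.21 with an estimated correlation (adjusted p = 0.449). The S set lay between -0.28 and 0.035 in MCF7, above 0 and not called without MCF7 ROS low replicate 2. Its difference between lines lay between -0.17 and 0.15, turning to 0.15 and called without MCF7 ROS low replicate 1. The G1 set lay between -0.31 and -0.03 in MCF7 and between -0.20 and -0.06 for the mean of both lines. Its difference between lines lay between -0.07 and 0.21. Of the other set values, 275 stayed on their side of the threshold, 27 lost a call and 14 gained one. Of the values of the 4 printed genes, 218 stayed called and 63 lost the call, all 63 within a single line. Choosing between probe sets, the planned lists and the RNA quality controls could not be run. Changes of genes near the pseudocount are understated.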

Other observations

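The splits for the correlation with the replicate block and the use of the S score, alone and against the G2/M score, to weigh the G2/M fall were chosen after the results were seen. In the fit without the block, median sizes of the genes called for the mean of both lines differed between the lines by direction. This difference was not tested. The 39 that rose had a median of 0.62 in MCF7 and 0.95 in HCT116, and 29 of them rose more in HCT116. The 121 that fell had a median of -1.23 in MCF7 and -0.85 in HCT116, and 98 of them fell more in MCF7. With the replicate block, 153 of the 350 that rose did so more in HCT116, so the pattern among rising genes was not seen there, while 282 of the 430 that fell did so more in MCF7. Without the block, 0 of these genes were called as different between the lines. With the block 21 genes were called as different, among them ENSG00000153234, one of the 39 that rose (limma adjusted p = 0.0326).

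The S markers differed more between MCF7 replicates than between the gates. The SD of the S score was 0.32 over the 3 MCF7 ROS-low arrays and 0.14 over the ROS-high arrays, against a difference between the gates of -0.12. For the G1 score these SDs were 0.28 and 0.11, against a difference of -0.16. All these SDs leave out the pairing by replicate number. The MCF7 pair differences lay between -0.28 and 0.07 for S (SD 0.18) and between -0.30 and 0.06 for G1 (SD 0.19). In HCT116 the SDs of the S score were 0.09 and 0.04, with a difference of -0.14 and a fall in each of the 3 pairs (between -0.20 and -0.07).

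The fall of the G2/M markers had a median of -0.60 for the mean of both lines. It was -0.60 at its smallest after quantile normalization or centring each array on its median. Camera gave adjusted p = 4.67e-29 after quantile normalization, and these values argue against array scaling. Camera's adjusted p of 1.37e-28 after centring adds little. Centring shifts all genes of an array alike, so camera's comparison with all other genes could hardly change. Whether the ROS-low gate held fewer dividing cells stays open. The fall of the G2/M set is the pattern itself, and the S score, which was 0.13 lower, did not pass (exact permutation p = 0.225). That permutation leaves out the pairing by replicate number. With the pairing kept, the S score was lower in 5 of 6 pairs. Exact sign flips gave p = 0.0625, which did not pass either. Camera put the S set lower with the preset correlation (adjusted p = 0.00378, and 0.0046 with the replicate block). With an estimated correlation it did not (adjusted p = 0.303). The difference between the gates in the G2/M score minus that in the S score was -0.66 in MCF7 and -0.44 in HCT116. Exact permutation gave p = 0.01 for both lines together. It also leaves out the pairing, and exact sign flips of 6 pairs cannot give a p under 0.031. This difference does not separate fewer dividing cells from a gate that follows cell size, which was not tested. The G1 set was not called higher in the ROS-low gate, and the stem cell marker sets were not tested for how well they follow phase in these lines.

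Of the 160 genes called for the mean of both lines, 75.6% fell in ROS-low cells. The excess was not seen at an unadjusted p under 0.05, where 582 genes were higher and 553 lower, and the share that fell was 55.1% of the 780 genes called with the replicate block. The share among called genes without the block was at least 75.5% after quantile normalization or median centring, which argues against array scaling. Among the 69 called genes outside the cell cycle marker table it was 53.6%, so cell cycle genes may account for most of the excess among called genes, as a hypothesis. With the replicate block the share outside the table was 43.4% of 551 genes.

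The correlation of the differences between the lines was 0.356. It was 0.249 over the 9957 genes outside the marker table. The table need not hold every cell cycle gene, and 37 of the 121 genes that fell lie outside it, so the part that cell cycle genes have in the correlation stays open. It was 0.544 over the 3679 brightest genes, which argues against dim genes as its source. Pair differences did not correlate more between the lines for the same number than for different numbers (-0.017). The mean correlation was 0.178 for 3 pairs of the same number (0.116 to 0.244) and 0.195 for 6 of different numbers (0.107 to 0.267). These ranges overlap, and a day's effect common to both gates cancels in the differences. The comparison therefore does not decide whether arrays with the same number in both lines shared a day. What else the lines share stays open, the ROS gate among them, and no biological explanation other than cell cycle genes was tested here.

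Other splits of the arrays were compared with the gates. For the mean of both lines, 1 of 100 splits drawn within the lines, the real one, gave 160 genes, and the highest of the others gave 18. Only 18 of the 100 splits, the real one among them, part all 6 pairs, too few for a share under 0.05. The others of these 18 called 0 genes. Splits that part fewer pairs put differences between replicate numbers into the comparison, so they do not exclude chance. The split with 18 genes parts 2 pairs. With the replicate block, 1 of the 32 splits that part every pair gave 780 genes. The highest of the others, 21, was the split that exchanges the gates in all HCT116 pairs and so measures the difference between lines. The correlation between the lines was matched by 1 of 100 splits, the real one (highest other 0.197). Of the 32 splits that part every pair, 1, the real one, gave a correlation as high, the smallest share that 32 splits allow. The highest of the others was 0.275. The block leaves the correlation at 0.356, so this compares the same value with other splits and is not a second result. In MCF7, 2 of 10 splits gave at least the real 76 genes. The other one gave 78 and parts 1 pair, with both arrays numbered 1 on one side and both arrays numbered 2 on the other, which points to differences between replicate numbers; the blocked count was 418. In HCT116, 1 of 10 splits gave 15 genes and the highest other gave 1. A line's 10 splits are too few for a share under 0.05. For the difference between lines the real count is 0, which 100 of 100 splits reach whatever the data, so the splits say nothing about it. The highest other, 160, is the split that exchanges the gates of one line.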
